A study of Mus musculus with 16 samples.

How the data were processed

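RNA from primary mouse astrocytes exposed to amyloid-beta was sequenced after directional poly(A) library preparation, in 8 control and 8 APOA1 libraries. The authors deposited library-size-normalized counts (signal values), 1 value per gene and library, for 14637 genes, and every column was matched to a sample by its name. Per the submitters' processing notes, FastQC 0.12.1, MultiQC 1.27, STAR 2.7.11b, featureCounts 2.0.8, DESeq2 1.44.0, and the build GRCm39 were used, with no role or order given. The annotation release, the strand setting of the counting, and the filters are not given in the sources used here. Without a stated strand setting, reads of a gene and of an antisense or overlapping partner cannot be told apart, and reads of close paralogs could have been split or dropped. The lowest value above 0 of each library, or a simple fraction of it, was taken as the value of 1 read, and with it all values came out as whole reads within a tolerance of 1e-06. Every listed gene had at least 10 such reads in at least 8 libraries. Pairs of libraries of a group differed by a chi-square of 6.18 to 29.8 per degree of freedom over 56 pairs, so no library was counted as a duplicate.

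Deposited values were transformed to log2(value + 1), and genes with a value of at least 10 in at least 8 libraries were tested (14591 genes, with 46 below the filter). Fold changes are on this scale, which understates the change of low genes. The comparison of APOA1 with control used limma 3.58.1 with trend and robust empirical Bayes in R 4.3.3, group as the only term, and Benjamini-Hochberg adjusted p under 0.05. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, and matplotlib 3.10.9 served for tables and figures. The procedure was tested on reads simulated with the measured means and spread, of which 14543 genes passed the filter, with 8 libraries against 8. For this comparison it recovered 31.2% of genes changed 1.1-fold, 64% at 1.2-fold, 94% at 1.5-fold, and 96% at 2-fold, and 7 of 169 calls were false (4.14%). These shares hold at a depth of 56.6 to 76.6M reads per library, for few changed genes, and for genes simulated independently of each other. Genes of the data can vary together, so the share of false calls may not carry over to them. Far more genes were called in the data (3941), which loosens the cut set by the adjusted p. The shares can therefore understate the recovery there.

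Before the data were examined, 35 lists were fixed: 27 gene lists (cholesterol synthesis, cholesterol efflux and LXR targets, fatty acid synthesis, fatty acid oxidation, pan-reactive, A1 and A2 astrocyte genes, NF-kB cytokines and chemokines, interferon-stimulated genes, class I antigen presentation, complement, Alzheimer risk and familial genes, amyloid-beta clearance, NRF2 oxidative stress, endoplasmic reticulum and integrated stress, heat shock, lysosome and autophagy, cell cycle, extracellular matrix, neurotrophic and synapse-active factors, hypoxia and glycolysis, immediate-early genes, nuclear oxidative phosphorylation, metallothionein and zinc, mitochondrially encoded genes, sex-linked genes, and receptors of APOA1 and high-density lipoprotein) and 8 of cell type markers (astrocyte, microglia, neuron, oligodendrocyte lineage, endothelial, fibroblast and meningeal, mural, and ependymal and choroid plexus). Some genes are in several lists. Lists were tested by camera with a preset correlation of 0.01, adjusted over the 35 lists, as the planned main test. Camera with an estimated correlation and fry were planned beside it and adjusted in the same way. A further test of each list, the exact two-sided permutation of its mean log2 level per library, was planned for the 8 marker lists, the mitochondrially encoded, and the sex-linked genes (adjusted over 10 levels), and was extended to all 35 lists after the data were seen (adjusted over 35). Each list was thus tested in 4 ways.

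Genes were named by a rule fixed before the data were examined. Among genes past the threshold, predicted models left out, it takes the 12 largest rises and the 12 largest falls with a mean of at least 50 normalized counts in the higher group, the 5 smallest p-values, up to 4 members with the smallest p of each list described in detail, and Apoa1, Abca1, and Apoe where measured. Apoa1 was not analysed here, and some genes that the rule takes are not reported here. Genes named outside the rule are said to have been chosen after their values were seen.

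Alternatives changed 1 choice at a time, save that edgeR and DESeq2 also took the recovered reads as input and normalized them in their own way: a pseudocount of 0.5 or 8, no filter or a mean of at least 100, rescaling by trimmed means (TMM) or to equal totals, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on the recovered reads, the replicate number as a block, array weights, each library left out in turn, a minimum fold change, and medians in place of means for marker levels. After the data were seen, odd or even replicate number as a term, odd- or even-numbered libraries alone, relabelling within them, a correction for GC content and gene length, and the exact tests of list levels with each library left out were added. GC content and length came from a GENCODE annotation of the build GRCm38, another build than the authors', matched by symbol for 14118 genes (96.5%), and no coordinates were taken from it. The first form of that correction moved the median of each library and was replaced, after its result was seen, by one that keeps the median. For each count of calls 100 splits of the libraries were compared, the real one and others drawn at random, and the shares given include the real one.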

Results

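Gene expression was measured in primary astrocytes from the brain of wild-type mice. All 16 samples had been exposed to amyloid-beta, the peptide that accumulates in the plaques of Alzheimer's disease. In 8 of them APOA1 (apolipoprotein A-I, the main protein of high-density lipoprotein) was present at 10 µg/mL for 24 h, and the other 8 received the same volume of PBS and are called controls here. Normalized read counts were available for 14637 genes. Behind them lay 56.6 to 76.6M reads per library (M, mega), with 67.7 ± 6.15M in controls and 64.5 ± 6.24M with APOA1 (SD, n = 8 per group; two-sided exact permutation p = 0.314). The share of reads from mitochondrially encoded genes was 1.35% ± 0.126 in controls and 1.41% ± 0.0979 with APOA1 (exact permutation p = 0.322). The 10 most abundant genes of a library took 7.95% ± 0.142 of the reads in controls and 7.49% ± 0.0757 with APOA1 (exact permutation p = 0.000155, the smallest that 8 against 8 can give). Values for Apoa1 itself were not analysed here. The labels do not say whether the replicates came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

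The comparison asked how APOA1 alters the transcriptome of astrocytes that face amyloid-beta. With APOA1, camera called 5 lists lower. These were immediate-early genes, NF-kB-driven cytokine genes, genes of hypoxia and glycolysis, of cholesterol synthesis, and of the NRF2 response. Astrocyte, ependymal, microglia, and mural cell markers and cell cycle genes were called higher. With an estimated correlation between genes the calls on immediate-early genes (adjusted p = 0.0408) and ependymal markers (adjusted p = 0.0428) held and those on the other 8 lists were lost (adjusted p from 0.130 to 0.535). By limma with Benjamini-Hochberg adjustment, 3941 of 14591 tested genes (27.0%) changed, 2133 upward and 1808 downward. Most changes were small, with a median of 1.13-fold in either direction. A change of at least 1.5-fold was measured for 298 genes, 247 higher and 51 lower, and of at least 2-fold for 59 genes, 48 higher and 11 lower. The 8 APOA1 and the 8 control libraries did not overlap for 974 genes, 6.68% of those tested, where chance gives 0.0155%. Of 35 gene lists fixed beforehand, 10 were called by camera, 5 higher and 5 lower. Of 100 splits of the libraries, the real one included, 27 called at least as many lists. Nearly all the others among these divided the APOA1 libraries unequally and so can carry part of the APOA1 difference. Some also divided the odd- and even-numbered replicates unequally. The highest other split called 16 lists and 0 genes. Chance is therefore not excluded for the number of lists. Exact permutation of the mean level per library, adjusted over the 35 lists, called 17, these 10 and 7 more, and fry called these 10 and 8 more. Neither test compares a list with other genes, as camera does. Their calls on lists that camera did not call are given with those lists, and 15 lists were called by none of the 3 tests.

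Odd- and even-numbered replicates differed within each group, which the labels do not explain. Each group holds 4 of either kind. The APOA1 comparison was therefore repeated within each kind, and limma called 2550 genes in the odd-numbered and 2505 in the even-numbered libraries. Of these, 1364 were called in both with the same direction, where independent lists would share 227, and 6 with opposite directions. With 4 libraries against 4, a call can be lost for want of samples, so the log2 fold change is given beside calls lost within one kind. A test of the difference between the effects in the odd- and even-numbered libraries called 16 of the 35 lists by camera and 0 with an estimated correlation (6 at an unadjusted p under 0.05).

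**Figure D1:**
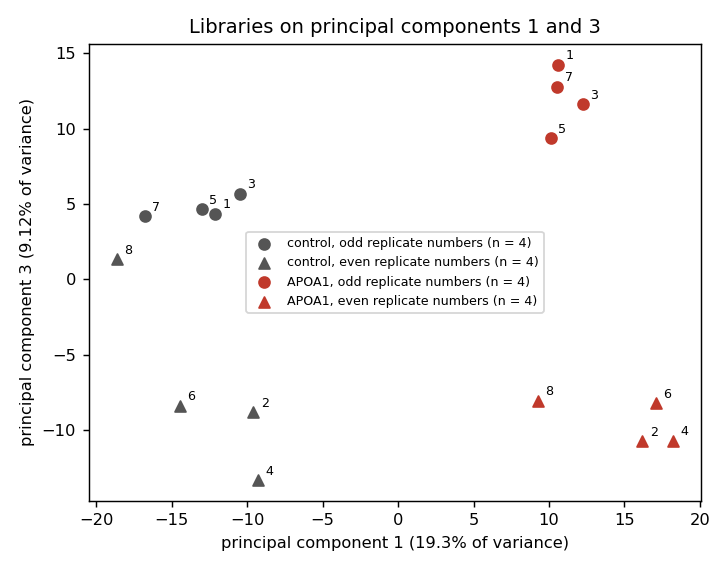
Each point is a library, placed by its score on principal component 1 (19.3% of variance, horizontal axis) and component 3 (9.12%, vertical axis) of log2 normalized counts. Gray marks controls, red marks APOA1, circles and triangles mark odd and even replicate numbers; the controls lie at or below -9.28 on component 1 and the APOA1 libraries at or above 9.29, and within each group the odd-numbered libraries lie above the even-numbered ones on component 3.

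Among the 12 genes with the largest rises, Fam180a went from 36.6 ± 9.0 normalized counts in controls to 109 ± 37.9 with APOA1 (SD, n = 8 per group; log2 fold change 1.5 ± 0.20 SE, limma adjusted p = 2.62e-06). Inmt, which encodes an N-methyltransferase, rose by 1.45 on the log2 scale and Cnmd, the gene of the antiangiogenic protein chondromodulin, by 1.441. The others were Fgd2 (1.274), the secretin receptor gene Sctr (1.23), the microglia marker Aif1 (1.23), the calretinin gene Calb2 (1.22), Fam107a (1.22), the DARPP-32 gene Ppp1r1b (1.17), the choline dehydrogenase gene Chdh (1.09), Arhgap36 (1.08), and Elobl (1.05), whose value is uncertain because its reads can be shared with its close copy Elob. Fam107a had the smallest p of the 12, with 409.5 ± 40.3 counts in controls and 954 ± 106 with APOA1 (limma adjusted p = 1.38e-12). Several of the 12 had low counts. Means in controls and with APOA1 were 27.8 and 65.3 for Fgd2, 39.1 and 83.4 for Ppp1r1b, and 41.2 and 81.9 for Arhgap36. The most abundant of the 12 was Elobl (5297 and 10990). Arhgap36 was not called in the odd-numbered libraries alone (log2 fold change 0.88, limma adjusted p = 0.211), nor was Ppp1r1b in the even-numbered ones (0.58, limma adjusted p = 0.105).

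The 12 largest falls were led by Rgs1, a regulator of G protein signaling, which went from 318 ± 55.6 to 109 ± 35.2 normalized counts (log2 fold change -1.58 ± 0.16 SE, limma adjusted p = 1.78e-07). The immediate-early genes Fosb (-1.38), Fos (-1.25), Arc (-1.25), Nr4a1 (-1.05), Ier2 (-1.002), and Egr1 (-0.95) followed, together with Zfp36 (-1.11), whose product promotes the decay of cytokine mRNAs. The cytokine genes Tslp (-0.87) and Il12b (-0.86), Nxph1, which encodes a neurexin ligand (-0.83), and the C-reactive protein gene Crp (-0.82) made up the rest. Crp was called neither in the odd-numbered libraries alone (-0.53, limma adjusted p = 0.215) nor in the even-numbered ones (-1.12, limma adjusted p = 0.0533). The 5 smallest p-values belonged to the catenin family gene Arvcf, which rose by 0.59 on the log2 scale (limma adjusted p = 8.11e-14), to Ier3 (-0.53), to Slco1a4, which encodes an organic anion transporter (0.75), to the antiproliferative gene Btg2 (-0.61), and to the calponin gene Cnn1 (0.59).

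**Figure D2:**
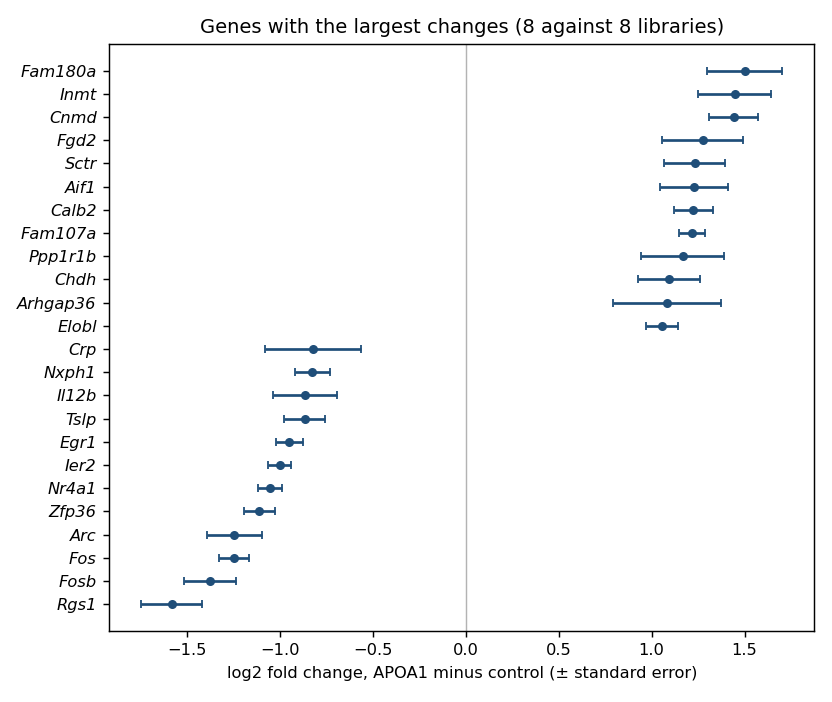
Log2 fold change (horizontal axis, APOA1 minus control, points) with its standard error (bars) of the 12 genes that rose most and the 12 that fell most among genes with a mean of at least 50 normalized counts in the higher group, 8 libraries per group. Values extend from -1.58 for Rgs1 to 1.5 for Fam180a.

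Immediate-early genes, which encode transcription factors and signaling regulators induced rapidly by stimulation, fell together. Of 15, 13 were lower with APOA1 and none higher (13 lower when adjusted over the list alone). Ier3 fell from 26841 ± 1155 to 18642 ± 688 normalized counts and Nr4a1 from 901 ± 104 to 432 ± 30.98 (log2 fold change -1.05 ± 0.07 SE, limma adjusted p = 4.71e-12). Jun fell by 0.30 on the log2 scale and Dusp1, which encodes a phosphatase that inactivates MAP kinases, by 0.69. The members that did not pass the test, named after their values were seen, were Fosl1 (-0.05, and -0.08 to -0.03 with 1 library left out) and Myc (0.01, and -0.00476 to 0.0201). The list averaged -0.66 (camera adjusted p = 1.47e-16, and adjusted p = 0.0408 with an estimated correlation). Its mean level in each APOA1 library lay below that in each control (exact permutation, adjusted p = 0.00109 over the 35 lists).

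Of 26 cytokine, chemokine, and regulator genes driven by NF-kB, 21 fell and 1 rose (22 and 1 when adjusted over the list alone). The hematopoietic growth factor genes Csf3 and Csf2 fell by 0.51 and 0.62 on the log2 scale. Cxcl2, the gene of a neutrophil chemokine, went from 16921 ± 1266 to 10780 ± 899 normalized counts (log2 fold change -0.65 ± 0.05 SE, limma adjusted p = 2.13e-07), and Nfkbia, whose product inhibits NF-kB, fell by 0.21. The gene that rose, named after its value was seen, was Traf1 (0.17). The list averaged -0.28 (camera adjusted p = 7.28e-14, and adjusted p = 0.130 with an estimated correlation). Its mean level separated the groups without overlap (exact permutation, adjusted p = 0.00109). Microglia, which can express several of these cytokines, had markers 0.42 log2 units higher in the APOA1 libraries.

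Astrocyte markers were higher, with 15 of 17 raised and 1 lowered, also when adjusted over the list alone. The intermediate filament gene Gfap rose from 127932 ± 5472 to 176419.8 ± 9412 normalized counts (log2 fold change 0.46 ± 0.03 SE, limma adjusted p = 4.18e-11). Aldh1l1, which encodes a folate enzyme, rose by 0.28, the acyl-CoA synthetase gene Acsbg1 by 0.31, and the connexin 43 gene Gja1 by 0.26. The member that fell, named after its value was seen, was the glutamate transporter gene Slc1a2 (-0.15, limma adjusted p = 0.0457). That call was lost without control replicate 1, 2, 6, 7 or 8 or APOA1 replicate 2, 4, 6, 7 or 8 (adjusted p from 0.0564 to 0.0847), with equal totals (0.0630), and in the odd-numbered libraries (log2 fold change -0.02, limma adjusted p = 0.798). The list averaged 0.28 (camera adjusted p = 7.07e-12, and adjusted p = 0.130 with an estimated correlation). Its mean level did not overlap between the groups (exact permutation p = 0.000155, adjusted p = 0.000777 over 10 levels).

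Lists that describe reactive astrocytes divided. Among 13 genes of general reactivity 5 rose and 6 fell (5 and 7 when adjusted over the list alone). Gfap and the filament gene Vim (0.35) were higher, whereas Timp1, which encodes a metalloproteinase inhibitor (-0.42), and the lipocalin 2 gene Lcn2 (-0.23) were lower, and the list as a whole was not called (camera adjusted p = 0.575). In the A1 list, defined by inflammatory stimulation, 2 of 12 genes rose, Ggta1 (0.37) and Fbln5 (0.37, and 0.23 in the odd-numbered libraries), and 1 fell, Srgn (-0.35), also when adjusted over the list alone (camera adjusted p = 0.380, fry adjusted p = 0.0150). Like the microglia markers, the A1 list was lower in odd-numbered libraries (-0.12, adjusted p = 0.0425 by camera with an estimated correlation). Fkbp5 had a log2 fold change of 0.12 (limma adjusted p = 0.0862). In the A2 list, defined by ischemia, 3 of 13 rose and 6 fell, also when adjusted over the list alone (camera adjusted p = 0.155). Its mean level was -0.09 with APOA1 relative to controls (exact permutation, adjusted p = 0.0222; fry adjusted p = 1.02e-06), and -0.06 without APOA1 replicate 1. With 1 library left out the exact permutation gave an adjusted p from 0.00272 to 0.0412. The cyclooxygenase 2 gene Ptgs2 fell from 13022 ± 1180 to 7694 ± 919 normalized counts (log2 fold change -0.76 ± 0.08 SE), the pentraxin gene Ptx3 fell by 0.34, Tm4sf1 fell by 0.27, and Cd109 rose by 0.34. Complement genes gave 5 rises and 1 fall among 13, also when adjusted over the list alone. Camera did not call the list (adjusted p = 0.0716), but its mean level was higher with APOA1 by 0.08 (exact permutation, adjusted p = 0.00483; fry adjusted p = 0.00484). Factor B (Cfb) fell by 0.50, C4b, which has a close paralog, rose by 0.20, Cd59a by 0.31, and Cfi by 0.33, the last not called in the even-numbered libraries alone (0.18, limma adjusted p = 0.304).

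Genes of the cholesterol synthesis list were lower: 12 of 25 fell and none rose (13 lower when adjusted over the list alone). Tm7sf2, which encodes a sterol reductase, went from 1670.1 ± 88.8 to 1367 ± 91.9 normalized counts (log2 fold change -0.29 ± 0.04 SE, limma adjusted p = 9.17e-06), and Acat2 fell by 0.18. The list averaged -0.11 (camera adjusted p = 1.48e-06, and adjusted p = 0.229 with an estimated correlation). Fatty acid synthesis genes gave 5 rises and 2 falls among 15, also when adjusted over the list alone (camera adjusted p = 0.412). Fatty acid oxidation genes gave 4 rises and 1 fall among 18, also when adjusted over the list alone, with a median (-0.01) opposite in sign to the mean (0.04; camera adjusted p = 0.677). Their mean level was called higher by the exact test (exact permutation, adjusted p = 0.0309) and not by fry (adjusted p = 0.212). The list averaged 0.08 in the odd- and 0.00216 in the even-numbered libraries. The difference of 0.08 was called by camera (adjusted p = 0.0113) and not with an estimated correlation (adjusted p = 0.252). The exact call was lost without control replicate 7 or APOA1 replicate 1, 3, 5, 6 or 7 (adjusted p from 0.0520 to 0.0611). Named after their values were seen, they included Pdk4 (0.20), Acaa2 (0.11), Cpt1a (0.07), and Angptl4 (-0.22). The log2 fold change of Pdk4 was 0.19 in the odd- and 0.21 in the even-numbered libraries and that of Acaa2 0.11 and 0.11, with no call in either kind alone (limma adjusted p = 0.0705 and 0.0908 for Pdk4, 0.114 and 0.140 for Acaa2). Cpt1a was not called without APOA1 replicate 2 (adjusted p = 0.0599) or in the even-numbered libraries (0.06, limma adjusted p = 0.354).

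Of 18 genes for cholesterol efflux and other liver X receptor (LXR) targets, 4 rose and 3 fell (5 and 3 when adjusted over the list alone). Apoe, which encodes the main lipid carrier that astrocytes secrete, rose from 180169 ± 10236 to 213405 ± 11035 normalized counts (log2 fold change 0.24 ± 0.03 SE, limma adjusted p = 6.57e-06). The phospholipid transfer protein gene Pltp rose by 0.22, Srebf1 by 0.14, and the apolipoprotein D gene Apod by 0.35. The list was not called (camera adjusted p = 0.600), and its median (-0.01) and mean (0.02) had opposite signs. The mean was 0.0106 without APOA1 replicate 2, 0.0113 without control replicate 5, and 0.0283 without control replicate 4. Abca1, which encodes the transporter that loads lipid onto APOA1, went from 39475 ± 1996 in controls to 37396 ± 1356 with APOA1 (log2 fold change -0.08 ± 0.03 SE, limma adjusted p = 0.0425). That call was lost without control replicate 1, 2, 7 or 8 or APOA1 replicate 2, 4, 6, 7 or 8 (adjusted p from 0.0578 to 0.0981), with equal totals (0.0922), and in the odd-numbered libraries (log2 fold change -0.02, limma adjusted p = 0.568). Of 7 measured receptors and partners of APOA1 and high-density lipoprotein, 1 rose, the cubilin gene Cubn (0.39), and 1 fell, Abca1, also when adjusted over the list alone (camera adjusted p = 0.765). Cubn was not called in the even-numbered libraries alone (0.34, limma adjusted p = 0.148). Amn had a log2 fold change of -0.52 (limma adjusted p = 0.212), -0.34 without APOA1 replicate 5, and -1.14 in the odd- and 0.10 in the even-numbered libraries. The sterol transporter gene Abcg1 had -0.10 (limma adjusted p = 0.411), and -0.06 without control replicate 8.

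Among 19 genes of glycolysis and the hypoxia response, 14 fell and 1 rose (16 and 1 when adjusted over the list alone). The phosphofructokinase gene Pfkl went from 37939 ± 1079 to 31027 ± 894 normalized counts (log2 fold change -0.29 ± 0.02 SE, limma adjusted p = 2.05e-10). Pdk1, whose product restrains pyruvate dehydrogenase, fell by 0.28, Bnip3 fell by 0.32, and the lactate dehydrogenase gene Ldha fell by 0.24, whereas another phosphofructokinase gene, Pfkp, named after its value was seen, rose by 0.21. The list averaged -0.16 (camera adjusted p = 1.63e-08, and adjusted p = 0.287 with an estimated correlation), and its mean level did not overlap between the groups (exact permutation, adjusted p = 0.00109). Of 17 NRF2-linked antioxidant genes, 8 fell and 3 rose, also when adjusted over the list alone. The cystine transporter gene Slc7a11 fell from 20330.2 ± 2188 to 11836 ± 692 normalized counts (log2 fold change -0.78 ± 0.06 SE), the sulfiredoxin gene Srxn1 fell by 0.21, and Taldo1, of the pentose phosphate pathway, fell by 0.18, while Gstm1, which has close paralogs, rose by 0.26. The list averaged -0.08 (camera adjusted p = 0.0156, and adjusted p = 0.429 with an estimated correlation). It was also lower in odd-numbered libraries, as microglia markers were (-0.07, adjusted p = 0.0308 by camera with an estimated correlation).

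Cell cycle genes rose, 19 of 22 upward and none downward (20 upward when adjusted over the list alone). Cenpf, which encodes a kinetochore protein, rose from 464 ± 54.8 to 666 ± 74.9 normalized counts (log2 fold change 0.52 ± 0.08 SE, limma adjusted p = 8.46e-06). The survivin gene Birc5 and the cyclin A2 gene Ccna2 rose by 0.46 and 0.46, and the replication licensing gene Mcm6 by 0.28. The list averaged 0.31 (camera adjusted p = 5.44e-09, and adjusted p = 0.384 with an estimated correlation). The list averaged 0.17 in the odd- and 0.45 in the even-numbered libraries, a difference of -0.28 (camera adjusted p = 1.51e-11, and adjusted p = 0.252 with an estimated correlation). Cenpf rose by 0.34 in the odd-numbered libraries. In these alone Birc5 (0.26, limma adjusted p = 0.0529) and Mcm6 (0.13, limma adjusted p = 0.0678) were not called.

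Of 35 genes tied to Alzheimer's disease by rare or common variants, 7 rose and 8 fell (9 and 9 when adjusted over the list alone), and the list was not called by camera (adjusted p = 0.468). Its mean level per library was 0.10 log2 units higher with APOA1 (exact permutation, adjusted p = 0.0218), and fry gave an adjusted p = 0.0838. Microglia markers, which share Trem2 with this list, were 0.42 higher with APOA1, and both lists were lower in odd- than in even-numbered libraries (by means of -0.11 for this list and -0.45 for microglia markers, adjusted p = 0.0191 and 0.00276 by camera with an estimated correlation). Sorl1, which encodes a sorting receptor for the amyloid precursor protein, rose from 5282 ± 212 to 7153 ± 351 normalized counts (log2 fold change 0.44 ± 0.03 SE, limma adjusted p = 3.39e-11). Apoe (0.24) and Slc24a4 (0.36) also rose, and the clathrin adaptor gene Picalm fell by 0.12. Among 18 genes for clearance and degradation of amyloid-beta 3 rose and 5 fell (4 and 5 when adjusted over the list alone). That list was not called (camera adjusted p = 0.677), and the test's downward direction was opposite to its median (0.01) and mean (0.00193), which ran from -0.00660 to 0.0116 with 1 library left out. Neurotrophic and synapse-active factors gave 4 rises and 4 falls among 16 (6 and 4 when adjusted over the list alone; camera adjusted p = 0.600). Chrdl1, whose product drives synapse maturation, rose by 0.37 and Sparcl1 by 0.18, and the genes of leukemia inhibitory factor, Lif, and of vascular endothelial growth factor, Vegfa, fell by 0.60 and by 0.40. Of 21 extracellular matrix genes 2 rose and 5 fell (4 and 5 when adjusted over the list alone; camera adjusted p = 0.548). Ccn1 (-0.40) and the laminin gene Lama4 (-0.21) were lower, and the smooth muscle gene Tagln (0.48) was higher. Tagln rose by 0.32 in the odd- and 0.64 in the even-numbered libraries, and the difference passed limma's test (adjusted p = 0.00979). The matrix list averaged -0.12 in the odd- and 0.10 in the even-numbered libraries, a difference of -0.22 (camera adjusted p = 2.48e-14, and adjusted p = 0.203 with an estimated correlation).

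Markers of other cell types that a primary astrocyte culture can hold were measured as well. Microglia markers were higher with APOA1: 9 of 18 rose and none fell, also when adjusted over the list alone. Aif1, which encodes IBA1, rose from 251 ± 68.5 to 584 ± 132 normalized counts (log2 fold change 1.23 ± 0.18 SE, limma adjusted p = 0.000111), and the complement genes C1qc, C1qb, and C1qa rose by 1.04, 0.82, and 0.87. Other members, named after their values were seen, moved less. The most abundant, Lyz2, had 109969 ± 18194 counts in controls and 130103 ± 23969.5 with APOA1 (log2 fold change 0.24, limma adjusted p = 0.184), and the log2 fold change was 0.14 for Csf1r, 0.02 for Cd68, and -0.03 for Ptprc. With 1 library left out these ran from 0.09 to 0.19 (Csf1r, lowest without APOA1 replicate 2), from -0.000437 to 0.0520 (Cd68, below 0 without APOA1 replicate 2), and from -0.08 to 0.02 (Ptprc, above 0 without control replicate 2 or APOA1 replicate 1 or 3). With odd or even as a term limma called Lyz2 and Csf1r higher (adjusted p = 0.000223 and 0.0198). Lyz2 was also called in the odd- (0.00134) and even-numbered libraries alone (0.00456), and Csf1r in the even-numbered ones (0.0249). Camera called the list (adjusted p = 4.07e-05, and adjusted p = 0.535 with an estimated correlation). The mean marker level of a library was 0.42 log2 units higher with APOA1 (exact permutation p = 0.00746, adjusted p = 0.0186). The difference was 0.35 in odd-numbered and 0.49 in even-numbered libraries, each with exact permutation p = 0.0286, the smallest that 4 against 4 can give.

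**Figure D3:**
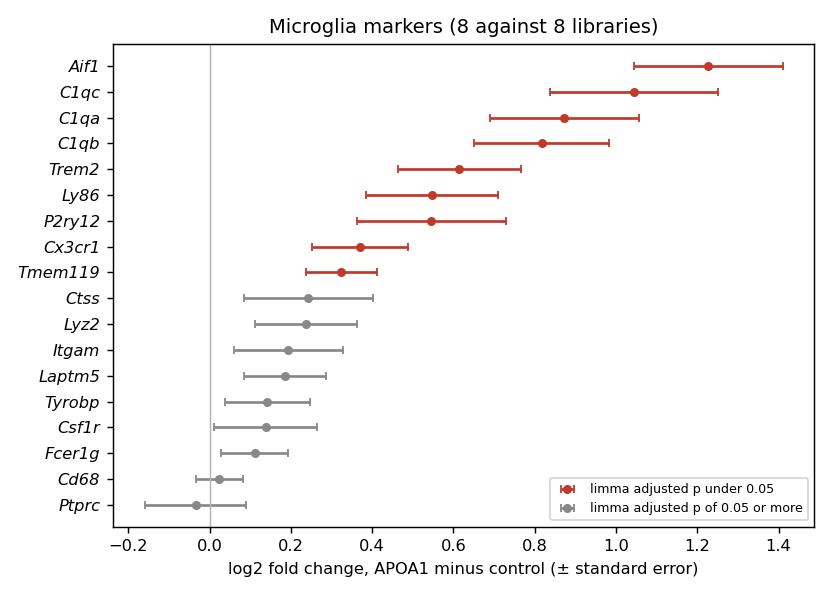
Log2 fold change (horizontal axis, APOA1 minus control, points) with its standard error (bars) of the 18 microglia markers, 8 libraries per group, with genes whose limma adjusted p lay under 0.05 in red. Values run from -0.03 for Ptprc to 1.23 for Aif1.

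Ependymal and choroid plexus markers were also higher, with 7 of 9 raised and none lowered (8 raised when adjusted over the list alone). Foxj1, the master regulator gene of motile cilia, rose from 16159 ± 624 to 20613 ± 689.7 normalized counts (log2 fold change 0.35 ± 0.03 SE, limma adjusted p = 6.87e-11). The cilium genes Cfap126 and Rsph1 rose by 0.42 and 0.33, and the folate receptor gene Folr1 by 0.59. The list averaged 0.42 (camera adjusted p = 1.18e-06, and adjusted p = 0.0428 with an estimated correlation), and its mean level did not overlap between the groups (exact permutation p = 0.000155, adjusted p = 0.000777).

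Of 8 mural cell markers 4 rose and none fell, also when adjusted over the list alone. The smooth muscle genes Cnn1 and Acta2 went from 4505 ± 246 to 6774 ± 332 and from 28552 ± 3956 to 40970.5 ± 3305 normalized counts, with a log2 fold change of 0.53 for Acta2 and 0.34 in the odd-numbered libraries. Myh11 (0.55, limma adjusted p = 0.0434) and Vtn (0.36, limma adjusted p = 0.0484) were called with less support. The call on Myh11 was lost without control replicate 2, 3, 6, 7 or 8 or APOA1 replicate 2, 3, 4, 5, 6 or 7 (adjusted p from 0.0524 to 0.0963) and in the odd-numbered libraries (0.17, limma adjusted p = 0.723), and that on Vtn without control replicate 1, 2, 4, 5, 7 or 8 or APOA1 replicate 2, 4, 7 or 8 (adjusted p from 0.0625 to 0.121), with array weights (0.0653), with GC content and gene length taken out (0.0600), and in the odd-numbered (0.22, limma adjusted p = 0.430) and even-numbered libraries (0.50, limma adjusted p = 0.0526). The list averaged 0.28 (camera adjusted p = 0.0400, and adjusted p = 0.384 with an estimated correlation). Its call was lost without control replicate 2, 4 or 8 or APOA1 replicate 2, 7 or 8 (adjusted p from 0.0501 to 0.0738), with equal totals (0.0526), array weights (0.0540) or a mean count of at least 100 (0.0926), and in the odd-numbered libraries, where the list averaged 0.05 (0.254), against 0.51 in the even-numbered ones.

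Endothelial markers gave 3 rises and no fall among 10, also when adjusted over the list alone (camera adjusted p = 0.0592, fry adjusted p = 0.000214). Slco1a4 rose from 3018 ± 187 to 5084 ± 285 normalized counts, the receptor gene Kdr rose by 0.55, and Emcn rose by 1.19. In the odd- and even-numbered libraries alone Emcn had log2 fold changes of 1.2768 and 1.0994 without a call (limma adjusted p = 0.0733 and 0.0713). Pecam1 had a log2 fold change of 0.49 (limma adjusted p = 0.0932). Oligodendrocyte lineage markers gave 6 rises and 1 fall among 13 (7 and 1 when adjusted over the list alone; camera adjusted p = 0.100, fry adjusted p = 0.00202). Cnp rose by 0.30, the myelin basic protein gene Mbp by 0.33, and Cldn11 by 0.58, and the transcription factor gene Olig2 fell by 0.13. In the odd-numbered libraries alone Mbp (0.20, limma adjusted p = 0.0859), Olig2 (-0.08, limma adjusted p = 0.159), and Cldn11 (0.43, limma adjusted p = 0.296) were not called, nor was Cldn11 in the even-numbered ones (0.74, limma adjusted p = 0.0504). The mean marker level of a library was higher with APOA1 for endothelial (0.34, exact permutation p = 0.000622, adjusted p = 0.00207), oligodendrocyte lineage (0.20, exact permutation p = 0.0120, adjusted p = 0.0239), and mural markers (0.28, exact permutation p = 0.0210, adjusted p = 0.0350). The call on the mural level was lost without control replicate 2, 4, 6 or 8 or APOA1 replicate 2, 4, 7 or 8 (adjusted p from 0.0531 to 0.0702), and that on oligodendrocyte markers, when adjusted over the 35 lists, without control replicate 4 or 8 or APOA1 replicate 3 or 6 (adjusted p from 0.0510 to 0.0544). In the odd- and even-numbered libraries the endothelial list averaged 0.17 and 0.51 and the oligodendrocyte list 0.10 and 0.31.

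Levels of neuron markers (0.02, exact permutation p = 0.759, adjusted p = 0.759) and of fibroblast and meningeal markers (0.08, exact permutation p = 0.239, adjusted p = 0.330) differed by less than the test could call. With 1 library left out the neuron level ran from -0.01 to 0.06, below 0 without APOA1 replicate 1 or 6. The neuron list averaged 0.07 in the odd- and -0.03 in the even-numbered libraries (camera adjusted p = 0.757 for the difference). Of 10 neuron markers 1 rose, Stmn2 (0.36), and when adjusted over the list alone 4 rose and 2 fell (camera adjusted p = 0.600, fry adjusted p = 0.0461). Of 12 fibroblast and meningeal markers 2 rose, Islr (0.35) and Ogn (0.74), and 2 fell, Lum (-0.54) and Dcn (-0.26), also when adjusted over the list alone (camera adjusted p = 0.677). The list averaged -0.05 in the odd- and 0.21 in the even-numbered libraries (difference -0.26, camera adjusted p = 0.000168, and adjusted p = 0.252 with an estimated correlation), and 0.03 without control replicate 8. These 5 genes were named after their values were seen.

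**Figure D4:**
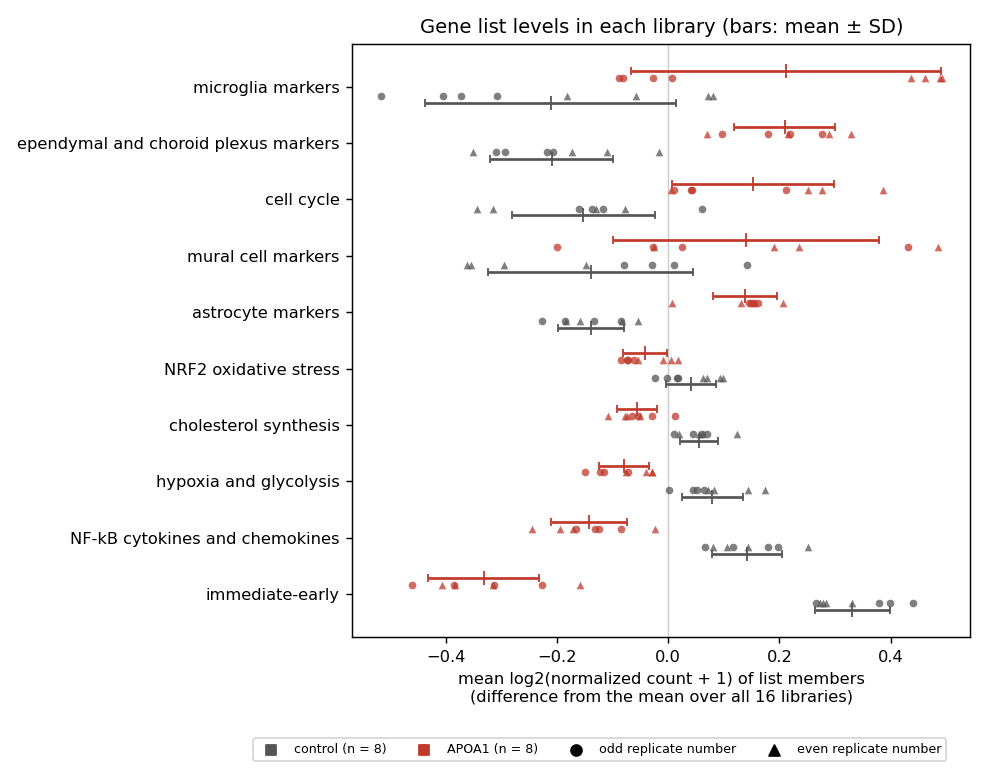
Mean log2 normalized count of the members of each of the 10 gene lists called by camera (horizontal axis, relative to the mean over all 16 libraries), with a point per library and bars for the mean and SD of each group of 8. Gray marks controls, red marks APOA1, circles and triangles mark odd and even replicate numbers; the groups do not overlap for the immediate-early, NF-kB, hypoxia, astrocyte, and ependymal lists.

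Interferon-stimulated genes showed no call as a list over all 16 libraries (mean 0.01, and -0.06 to 0.10 with 1 library left out, camera adjusted p = 0.765), with 2 of 22 raised, Ifit2 (0.25) and Cmpk2 (0.18), and none when adjusted over the list alone. In odd-numbered libraries the mean level of the list was lower with APOA1 (-0.22) and in even-numbered libraries higher (0.24), each with exact permutation p = 0.0286, the smallest that 4 against 4 can give. The difference between these effects was called by camera (adjusted p = 1.37e-33) and not with an estimated correlation (adjusted p = 0.117). Class I antigen presentation gave 1 rise among 14, Psmb9 (0.14; camera adjusted p = 0.765). Its genes averaged -0.06 in the odd- and 0.05 in the even-numbered libraries. The difference of -0.11 was called by camera (adjusted p = 8.3e-05) and not with an estimated correlation (adjusted p = 0.294). Genes of endoplasmic reticulum and integrated stress gave 3 rises among 18, Psat1 (0.34) and Phgdh (0.27) of serine synthesis and Pdia4 (0.11; camera adjusted p = 0.1205). The mean level of the stress list was 0.06 higher with APOA1 (exact permutation, adjusted p = 0.0309; fry adjusted p = 0.0238), and the exact call was lost without control replicate 2 or 8 or APOA1 replicate 3, 4, 6 or 8 (adjusted p from 0.0580 to 0.0646). The list averaged 0.01 in the odd- and 0.11 in the even-numbered libraries. Of 10 heat shock genes 1 rose, Hspb1 (0.21), and 3 fell, Hsph1 (-0.09), Hspa8 (-0.06), and Hsp90aa1 (-0.06; 4 fell when adjusted over the list alone; camera adjusted p = 0.314, fry adjusted p = 0.00596). Lysosome and autophagy genes gave 3 rises among 19, Tfeb (0.24), Ctsb (0.09), and Psap (0.05), and 2 falls, Mcoln1 (-0.17) and Lipa (-0.10; camera adjusted p = 0.677). Of 4 metallothionein and zinc genes Mt3 rose (0.36) and Slc30a1 fell (-0.18), with 1 rise and 3 falls when adjusted over the list alone (camera adjusted p = 0.734; median -0.09, opposite in sign to the mean of 0.00156, which ran from -0.00935 to 0.0133 with 1 library left out). For the antigen presentation, endoplasmic reticulum, and lysosome lists the counts were the same when adjusted over the list alone. The genes named in this paragraph were chosen after their values were seen. Their calls were lost without control replicate 1, 2, 3, 5, 6 or 7 or APOA1 replicate 2, 3, 4, 5, 6 or 7 (adjusted p from 0.0536 to 0.0835) for Psap, without control replicate 2, 3, 7 or 8 or APOA1 replicate 6, 7 or 8 (adjusted p from 0.0513 to 0.0715) for Hsp90aa1, without control replicate 1, 6, 7 or 8 or APOA1 replicate 2, 4, 6 or 8 (adjusted p from 0.0506 to 0.0605) for Cmpk2, and without control replicate 5 or APOA1 replicate 1, 3 or 7 (adjusted p from 0.0530 to 0.0553) for Lipa. In the odd-numbered libraries alone there was no call on Psmb9 (0.11), Pdia4 (0.07), Hspb1 (0.10), Hsph1 (-0.07), Tfeb (0.18), Slc30a1 (-0.10), Cmpk2 (0.05) or Hsp90aa1 (-0.07; limma adjusted p from 0.0549 to 0.568), and in the even-numbered ones none on Ctsb (0.06), Hspa8 (-0.06), Mcoln1 (-0.11), Psap (0.04), Lipa (-0.04) or Hsp90aa1 (-0.06; 0.116 to 0.604).

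No call was made by limma among 24 nuclear genes of oxidative phosphorylation (camera adjusted p = 0.734), 7 mitochondrially encoded genes (camera adjusted p = 0.386) or 4 sex-linked genes (camera adjusted p = 0.765), over all genes or adjusted over the list alone. At an unadjusted p under 0.05 limma gave 1, 0, and 0 genes of these lists, edgeR called 0, 0, and 0, and DESeq2 called 0, 0, and 0. The mean levels of the mitochondrially encoded (0.07, exact permutation p = 0.264, adjusted p = 0.330) and sex-linked genes (-0.02, exact permutation p = 0.627, adjusted p = 0.696) were not told apart between the groups. The mitochondrial difference was 0.04 without control replicate 4, and the sex-linked one ran from -0.0325 to 0.00135 with 1 library left out, above 0 without control replicate 8.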

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

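The test for a library that stands apart was set before the data were examined, but 57 of the genes it covers were named only after their values were seen. It compares the gap between the highest or lowest library of a group and its nearest neighbor with the range of the group, and marks a ratio above Dixon's 95% critical value for 8 libraries. Of 398 groups of 8 values, 18 were marked, where chance marks about 1 in 20 (19.9 of these).

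APOA1 replicate 8 stood apart in 5 values. Its astrocyte marker level was 0.01, below the 0.13 to 0.21 of the other 7 (ratio 0.617). It also had the lowest Elobl, 8321 normalized counts against at least 10609 (ratio 0.569), and the lowest Sparcl1, 28181 against at least 30213 (ratio 0.531). Ier3, at 20134 against at most 18835 (ratio 0.613), and Csf2, at 880.4 against at most 717 (ratio 0.610), were highest there. In these 5 values the library lay toward the control group.

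In APOA1 replicate 2 the level of the efflux and LXR list was highest, 0.07 against at most 0.02 (ratio 0.566), Slco1c1 was highest, 1059.5 normalized counts against at most 888 (ratio 0.627), and Phgdh lowest, 3963 against at least 4326 (ratio 0.557). Control replicate 8 had the highest Tslp, 503 against at most 348 (ratio 0.703), the highest Slc1a2, 50389 against at most 45154 (ratio 0.546), the highest Saa2, 2823 against at most 2624 (ratio 0.564), and the lowest Hspb1, 1466 against at least 1612 (ratio 0.611).

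Control replicate 4 had the highest Chdh, 90.3 normalized counts against at most 61.7 (ratio 0.564), the highest Srxn1, 11217 against at most 10239 (ratio 0.534), and the highest Psap, 167388 against at most 161020 (ratio 0.619). Folr1 was lowest in control replicate 6, 442 against at least 662 (ratio 0.746), and Hspa8 in control replicate 1, 60843 against at least 62300 (ratio 0.631). The level of neurotrophic and synapse-active factors was lowest in control replicate 3, -0.28 against at least -0.06 (ratio 0.676).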

How the results depend on the processing

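The fits on odd or even replicate numbers, the correction for GC content and gene length, and the exact tests of list levels with 1 library left out were chosen after the results were seen. Over all 16 libraries, counts of changed genes ran from 3719 (equal totals, 63.6% higher against 54.1%) to 4288 (odd or even as a term), with 3871 by edgeR and 4172 by DESeq2 on recovered reads, of which 3792 and 3921 were shared with limma in the same direction. Leaving out 1 library gave 3483 to 4001 genes and 9 to 11 lists called by camera, and 5 to 6 of the 10 planned levels called by exact permutation. That test, adjusted over 35 lists, also called fatty acid synthesis without control replicate 3 or APOA1 replicate 4 or 8 (adjusted p from 0.0338 to 0.0474) and neurotrophic factors without control replicate 1, 5 or 7 or APOA1 replicate 1 or 8 (adjusted p from 0.0340 to 0.0490). The odd-numbered libraries alone called 2550 genes (1042 lower) and the even-numbered ones 2505 (1011 lower), with fewer samples. An absolute log2 fold change of at least 0.5 left 459 genes, 384 higher and 75 lower, by its construction. Of the lists, 2 were called with an estimated correlation and 18 by fry, which tests each list against no change and not against other genes. Of the genes called by limma and the lists called by camera over all 16 libraries, no list and only 2 genes changed sign under the alternatives run. Both genes did so in the odd-numbered libraries and were picked out after their values were seen. They were Cenpe (0.27 over all, -0.07 there) and Slain1 (-0.11 and 0.003399), neither called there (limma adjusted p = 0.662 and 0.969). The mean of the neuron list, which fry called and camera did not, also changed sign, as given with the results. With the replicate block 4120 genes (2292 higher, 1828 lower) and 11 lists were called. Same-numbered libraries deviated together with correlations of -0.0579 to 0.145, and only replicate 4 correlated best with its own number, so the numbers were not taken to pair the samples. Besides the changes given with the results, the endothelial list gained a call with edgeR (0.00726), DESeq2 (0.00759), the block (0.0451), and without control replicate 4 (0.0489) or 5 (0.0370) or APOA1 replicate 1 (0.0367) or 3 (0.0377), as adjusted p by camera, and the complement list with array weights (0.0464) and without APOA1 replicate 4 (0.0436) or 6 (0.0457). The odd-numbered libraries added camera calls on the interferon-stimulated (1.24e-06), class I (0.0459), complement (0.00181), and extracellular matrix lists (0.000138), and the even-numbered ones on the interferon-stimulated (2.6e-10), endoplasmic reticulum (0.00836), oligodendrocyte (0.0252), and endothelial lists (0.00204). Fkbp5 gained a limma call without APOA1 replicate 5 (0.0468) and Pecam1 without control replicate 4 (0.0308). Correction for GC content and length ended the calls on Acaa2 (0.0522), Psap (0.0860), and Lipa (0.0811), equal totals those on Lipa (0.0558) and Hsp90aa1 (0.0883), and array weights (0.0528), the block (0.118) or odd or even as a term (0.0525) that on Slc1a2. Csf1r, Lyz2, Lrrc25, and Msr1 gained limma calls with the block and with odd or even as a term. Both terms are balanced between the groups and cannot move a fold change, so these calls came from the spread left in the fit. The causes of the other changes of calls were not tested. Small changes can go uncalled at this depth and number of libraries, which limits what can be said of genes without a call. The simulated recovery of 31.2% at 1.1-fold came with fewer changed genes and so a stricter cut than in the data.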

Other observations

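The 8 gene families in the next paragraphs, the exact tests within odd- and even-numbered libraries, the tests of microglia share and of unequal microglia markers, and the fit with odd or even as a term were chosen only after the results were seen. The correction for GC content and length was added after the first results and revised after its own was seen. The splits of odd against even libraries were drawn after that structure was noticed, and the bounds for calling the source open in the tests of microglia share and of the interferon-stimulated genes were tightened after their values were seen.

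Genes of motile cilia rose beyond the ependymal list. Of 46 Cfap genes, which encode cilium- and flagellum-associated proteins, 28 rose and 1 fell (camera adjusted p = 0.0135 with an estimated correlation), among them Cfap54 (0.41) and Cfap91 (0.47). Of 13 axonemal dynein heavy chain genes 7 rose and none fell (adjusted p = 0.0342 with an estimated correlation), and Dnah9 went from 1101 ± 116 to 1649.5 ± 97.7 normalized counts (SD, n = 8 per group; limma adjusted p = 7.98e-09), with Dnah6 up by 0.54. Of 14 smooth muscle contractile genes 12 rose and none fell (adjusted p = 0.0262 with an estimated correlation), including Myl9 (0.49) and Lmod1 (0.50). Of 10 genes that handle thyroid hormone 5 rose and 1 fell (adjusted p = 0.0298 with an estimated correlation). Dio3, which encodes the deiodinase that inactivates the hormone, rose from 356 ± 45.9 to 726 ± 69.5 normalized counts (limma adjusted p = 1.43e-10), and the transporter gene Slco1c1 rose by 0.57.

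Acute-phase protein genes fell, with 11 of 13 lower and 2 higher (adjusted p = 0.0246 with an estimated correlation). Saa2, whose reads can be shared with Saa1, fell from 2587 ± 114 to 1748 ± 89.0 normalized counts (limma adjusted p = 4.71e-12) and Orm2 fell by 0.46. Of 12 CXC chemokine ligand genes 8 fell and 1 rose (adjusted p = 0.0246 with an estimated correlation), with Cxcl16 down from 12081 ± 557 to 9454 ± 381 and Cxcl1 from 42254 ± 3019 to 26429 ± 2566. Of 77 cytosolic ribosomal protein genes none rose and 1 fell, Rpl39l (-0.77, limma adjusted p = 0.0205), a call lost without control replicate 3 (adjusted p = 0.0545) and in the even-numbered libraries (-0.40, limma adjusted p = 0.469), and the family was not called (adjusted p = 0.945). Of 17 circadian clock genes 3 rose, Dbp (0.22) among them, and 4 fell, Bhlhe40 (-0.16) among them, with no call on the family (adjusted p = 0.945). Families were chosen because members stood out, so their tests are not independent of the choice. Fixed lists also hold 4 acute-phase, 4 smooth muscle, 4 CXC, 2 thyroid, 1 Cfap, and 1 dynein genes of these, and none of the ribosomal or clock genes.

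The 3941 genes changed by APOA1 were not matched by any other of 100 splits of the libraries into 8 and 8 (1 split as large, the real one). A chance division of these libraries therefore seldom gives so many. If libraries share a culture, the splits cannot exclude a chance difference between cultures. The highest other split, with 2275 genes, exchanged the labels of control replicate 4 and APOA1 replicate 8. Of 100 splits, the real one included, 27 called at least 10 lists by camera, and the highest other called 16. Nearly all the others among these divided the APOA1 libraries unequally, so they can carry part of the APOA1 difference. Among splits with 4 APOA1 libraries on either side, the highest called 12 lists, with 6 odd-numbered libraries on the same side. Splits that also had 4 odd-numbered libraries on either side called 0 to 7 lists. These were few, so chance is not excluded for the number of lists. The tables argue against GC content and length as causes of the number of genes, as 4011 were called after their removal and 3838 before, 3500 of them shared, while the 4288 called with odd or even as a term are no test of the numbering, since both groups hold 4 of either kind and the term cannot move a fold change. An effect of APOA1 on the cells remains a hypothesis for the number of genes, beside differences between samples that the labels do not describe.

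Odd- and even-numbered replicates differed in 703 genes, 561 lower and 142 higher in odd-numbered ones. They were led by the myeloid genes C1qa (-0.67), Lrrc25 (-0.46), C1qb (-0.60), Pirb (-0.53), and Msr1 (-0.55). Of 100 splits, 1 gave as many, the real one (highest other 5). As this split was tested because its difference had been noticed, the count does not exclude chance. Of the lists, 16 of 18 microglia markers and 20 of 22 interferon-stimulated genes were lower in odd-numbered libraries, and the most abundant marker, Lyz2, had 101463 normalized counts there and 138609.5 in even-numbered ones. A larger share of microglia in even-numbered samples may underlie this, and with the marker level as a term 0 of these genes were still called by limma, the only tool run here (35 at an unadjusted p under 0.05), but group and marker level explain 89.3% of the odd or even term, so share and numbering cannot be told apart. The APOA1 differences of the interferon-stimulated list in odd (-0.22) and even libraries (0.24) differed by -0.46. Of this, -0.32 was left after they followed the microglia markers (exact permutation p = 0.246), a test that left the source open. The slope used there (1.03, between libraries of a group) includes the odd against even difference of both lists (-0.47 for interferon-stimulated genes, -0.45 for microglia markers). It therefore does not show that the list follows microglia share. Microglia markers were higher with APOA1 in odd- (0.35) and even-numbered libraries (0.49), while the list was lower in the former and higher in the latter. The groups did not overlap in any of these comparisons. Share alone would move the list in the same direction in both kinds. These values argue against microglia share as the only source of both APOA1 differences of the list. Effects of APOA1 that differ between odd and even were called for 16 genes, including Zbp1, Isg15, Bst2, and Usp18, but 5 of 100 splits, the real one included, gave as many (highest other 343), so chance is not excluded, though all 4 larger splits part the APOA1 libraries by odd and even and mix the controls, which points to that structure, and no biological explanation was tested.

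Microglia markers were higher with APOA1 within odd and even libraries alike, with an exact permutation p of 0.000408 by relabelling within them, the smallest that 4900 relabellings can give, which is no test of the numbering because it is balanced between the groups. A larger share of microglia would raise all 18 markers in step, of which Trem2 is also in the Alzheimer list. After each marker followed the others within groups, the APOA1 differences left spread by 0.300 between markers (SD, from -0.43 for Ptprc to 0.71 for Aif1). Relabelling gave a median of 0.0877 (exact permutation p = 0.000408). The real grouping also had the largest marker difference, so errors in how markers follow each other widen its spread most. The test therefore cannot decide whether a larger share is the whole source. The abundant markers Lyz2 (0.24) and Csf1r (0.14) had smaller log2 fold changes than Aif1 (1.23) and were called only with odd or even or the replicate as a term, or in part of the libraries. A changed state of microglia, or expression of Aif1 and C1q genes in other cells, may account for the unequal log2 fold changes and was not tested.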
